A study of Mus musculus with 19 samples.

How the data were processed

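The series holds 19 GEO samples of mouse tissue, 1 per tissue, and samples were grouped by the tissue in their titles. Per the labels' protocols, RNA was extracted with Trizol, cleaned with a column kit that included DNase treatment, and checked on a Bioanalyser. The library kit, strandedness, aligner and genome build are not given in the sources used here. DESeq2 is named in the submitters' processing notes without a version or role.

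The authors deposited FPKM for 13 tissues in one table, a group table of FPKM for the same 13 tissues, and raw read counts with a further FPKM table for 6 tissues. Of the columns of the group table, 12 were identical to the first, and kidney was a mean. Genes with reads in the single kidney library alone stood at exactly 3 times that mean, which makes it the mean of 3 kidney libraries including the single one. The mean of the 2 remaining libraries was computed from it and used only as an alternative.

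The deposited FPKM was read from its values as the reads of a gene, divided by a gene length and by the library's total of assigned reads. Before any length was completed from the annotation, 94.8% of the lengths of 16105 genes with several transcripts equalled the annotated mean transcript length within 1 base, and the remainder did not. Whole reads were recovered from it: the library total from the smallest value per unit of length, and the length as the common denominator of a gene's values. Where all reads of a gene shared a factor, the multiple within 1 base of the annotated mean transcript length was taken (1942 genes). The recovered reads summed to at least 99.9966% of each library's total. For 5 of 54532 gene rows no length was recovered and the annotated mean was used. Of the identifiers, 99.93% were found in GENCODE M21 (GRCm38), and 98.3% of those had identical coordinates. Coordinates in the text are those of the deposited table.

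FPKM of the 6 tissues in the authors' second FPKM table used another length and DESeq2-type size factors, and was recomputed exactly from the deposited counts, so it is not on the scale of the first table. For comparisons across all 19 tissues, FPKM was recomputed from the deposited counts with the lengths and formula of the first table. The main kidney comparisons used the 13-tissue table alone.

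A gene was called enriched in a tissue when its FPKM was at least 1 and its FPKM plus 0.1 was at least 4 times the highest other tissue's FPKM plus 0.1. Tau was computed on log2(FPKM + 1) with a threshold of 0.9. A gene was shared by kidney and 1 other tissue when both were at FPKM 1 or more, the lower of them passed the 4-fold rule against the remaining tissues, and the gene was not kidney-enriched. Folds in the text are ratios of FPKM without a pseudocount, and their 95% intervals are exact binomial intervals (Clopper-Pearson) on the recovered reads. In one kidney library a floor of 3 reads is 0.178 reads per 1000000. With 1 column of values per tissue no p-values were computed.

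Gene lists for nephron segments, transporters, metabolism, endocrine genes and transcription factors, tissue markers, and markers of cells or organs that a dissection could also hold were fixed before the data were examined. The median log2 ratio of each kidney list was placed among 10000 random lists of the same size, drawn from genes at FPKM 1 or more in any tissue within 20 bins of mean log2 expression. Named genes were taken from the 12 with the largest ratio among enriched genes at kidney FPKM 10 or more, the 12 with the highest kidney FPKM, members of the lists, the 4 shared genes with the highest kidney FPKM for each of the 3 leading partner tissues, and the enriched gene with the highest FPKM per tissue. Predicted gene models were counted but not named, and not every gene under these rules is named in the text. The sex-linked genes and genes named for leaving the list were chosen after their values were seen.

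The rule was tested on simulated reads of 26586 genes drawn at the real library sizes, with 200 genes raised in kidney. Every other tissue was set at the gene's mean FPKM, and only counting noise was added. The rule called 0 of 50 genes raised 2-fold, 48 of 50 raised 8-fold (96.0%) and all 50 raised 16-fold, and 0 of 26386 unchanged genes. Genes raised 2-fold or unchanged could hardly pass a 4-fold rule under this noise. The simulation therefore gives no rate of false calls for real tissues, which differ by more than counting noise. Read recovery on the same simulated values returned all reads for 99.99% of genes. Each simulated gene had a level above 0 in all tissues, so this share may not hold for real genes with reads in few libraries. Alternatives covered the pseudocount, level, fold, scaling, tissues and kidney libraries used. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. Genes annotated as antisense, overlapping genes and members of gene families share reads, and how the authors' counting assigned these is not given in the sources used here.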

Results

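The series asked which genes are specific to the mouse kidney. Total RNA was sequenced from 19 tissues of C57BL/6J mice labelled as 8-week-old males on a chow diet, with 1 sample per tissue. One table gave FPKM (fragments per kilobase of transcript and per 1000000 assigned reads) for kidney and 12 other tissues. A second table gave raw read counts for the 6 remaining tissues, which were bone, brown adipose tissue (BAT), intestine, spleen, lung and skin. Reads assigned to genes ranged from 11135276 in colon to 17263334 in parathyroid, and the kidney library held 16895878. No tissue had replicate libraries in separate columns, so genes were called by fixed rules without a test. The intervals of folds below are 95% exact binomial intervals that cover counting error only.

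The labels of the libraries were first set against transcripts that mark sex and tissue. Xist, the noncoding RNA of the inactive X chromosome, was at 90.9 FPKM in kidney (14620 reads) and 97.5 FPKM in eye (15468 reads). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 3 reads in the kidney library and 3 in the eye library. Aorta had both Xist (22.1 FPKM) and the Y-linked transcripts (80.5 FPKM summed), and so did parathyroid, with 59.7 and 35.7 FPKM. In the 15 other tissues Xist was at most 0.0683 FPKM. The libraries labelled kidney and eye therefore went against the label male by these transcripts, and all comparisons below are of "the library labelled kidney" with the other libraries.

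**Figure D1:**
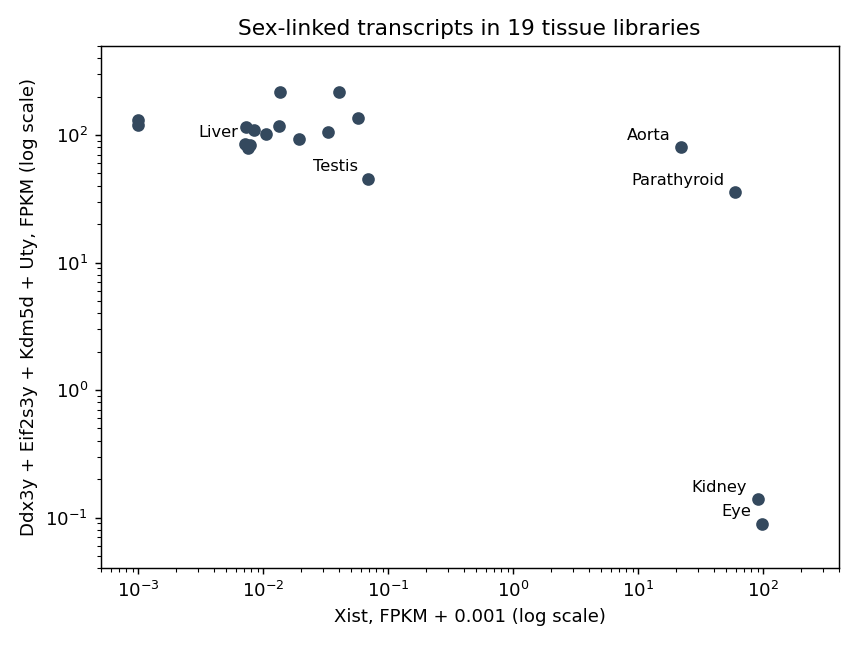
Xist against the summed FPKM of 4 Y-linked genes, both on log scales, with 1 point per tissue library and 0.001 added to Xist. Kidney and eye lie at the lower right with Xist at 90.9 and 97.5 FPKM, aorta and parathyroid carry both kinds of transcript, and the 15 other libraries lie at the upper left.

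Tissue markers followed the labels for most libraries: of 163 markers of the 18 tissues other than kidney, 145 were highest in the tissue they mark (89.0%, interval 83.1 to 93.3%). All markers were highest in their own library for liver, heart, skeletal muscle, eye, lung, thymus, testis, stomach, intestine and parathyroid. The lowest share was in BAT, with 5 of 8 (Elovl3 was highest in liver, Cox7a1 in heart and Dio2 in brain). Brain and spleen had 6 of 9 each, with the neuronal genes Nrgn and Camk2a highest in white adipose tissue (WAT) and skeletal muscle and the erythroid genes Klf1 and Epb42 in bone. Bone had 8 of 11, WAT 7 of 9 (Plin1 and Fabp4 were highest in BAT), skin 8 of 10, and colon and aorta 8 of 9 each. Some libraries also held markers of other organs. The parathyroid library had thyroglobulin (Tg) at 57706 FPKM beside parathyroid hormone (Pth) at 7211 FPKM, and the aorta library had Tg at 5505 FPKM and Pth at 621 FPKM. The WAT library, labelled epididymal fat, had the epididymal gene Crisp1 at 11117 FPKM.

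The question of kidney-specific expression was addressed by taking genes with a kidney FPKM of at least 1 and at least 4-fold above the highest of the 12 other tissues in the same table, with 0.1 FPKM added to both. This gave 263 kidney-enriched genes among 14248 genes at FPKM 1 or more in kidney. Among them were genes of membrane transporters of the proximal tubule, such as the sodium/phosphate cotransporter gene Slc34a3, the sodium/glucose cotransporter gene Slc5a2 and the organic anion transporter gene Slc22a8, all above 29-fold. In total 43 of the enriched genes were solute carriers, 23.9% of the enriched protein-coding genes against 2.25% of all protein-coding genes at FPKM 1 or more in kidney. Of the 263 genes, 180 were protein coding, 29 were lincRNAs and 18 were annotated as antisense. Predicted gene models made up 82 of them. The enriched genes took 9.41% of the reads of the kidney library.

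By ratio, the leading gene was Ugt1a2, a UDP-glucuronosyltransferase (ENSMUSG00000090171, chromosome 1, 88200601 to 88218997), at 252 FPKM in kidney and 0.122 FPKM (3 reads) in colon, the highest other tissue (interval of the fold 708 to 10033). Slc7a12, an amino acid transporter gene (ENSMUSG00000039710, chromosome 3, 14480697 to 14505830), was at 173 FPKM against 0.279 FPKM in WAT (618-fold, 284 to 1686). Cyp4a14, a fatty acid hydroxylase, was 108-fold above liver (89.7 to 131). Slc5a12, a lactate transporter gene, was 76.3-fold above liver (59.8 to 99.0). Slc6a18, an amino acid transporter gene, was 60.6-fold above liver. The thiazide-sensitive cotransporter gene Slc12a3 was 57.0-fold and the vitamin D 24-hydroxylase Cyp24a1 56.5-fold above liver. Cubn, the receptor cubilin, was 53.0-fold above liver. Slc22a19 (62.3-fold), Slc22a29 (69.2-fold) and the thioesterase Acot3 (56.6-fold) have close paralogs, as do Ugt1a2 and Cyp4a14, so their values are uncertain where counting divided shared reads. Ugt1a2 also lies within the coordinates of Ugt1a10 on the same strand (chromosome 1, 88055388 to 88219004). Its values in all tissues therefore depend on how reads of the overlap were assigned. Slc22a8 completed the 12, 45.7-fold above brain. Slc7a12 and Cyp4a14 are known to be higher in female mouse kidney, so their place cannot be separated from the sex of the RNA. The order depends on the liver library. Without it, and with 0.1 FPKM added, the ratio to the next tissue of the same table was 1787 for Cyp4a14, 767 for Slc12a3, 559 for Slc5a12, 194 for Cyp24a1, 139 for Slc22a19, 111 for Cubn and 92.2 for Slc6a18. No intervals were computed for these ratios. Some rest on values near the floor, such as 0.165 FPKM in heart for Slc5a12 and 0.133 FPKM in testis for Cyp24a1, and are imprecise. With the 6 further tissues added and liver left out, Slc5a12 was at 2.70 and Cubn at 1.47 times the next tissue.

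By level, the leading gene was Kap, the kidney androgen-regulated protein (ENSMUSG00000032758, chromosome 6, 133849851 to 133853762), at 13039.5 FPKM, although liver reached 2650 FPKM (4.92-fold, 4.85 to 4.99). As an androgen-regulated gene, Kap has a level and a fold that cannot be separated from the sex of the RNA. Pck1, the gluconeogenic enzyme PEP carboxykinase, was at 3892 FPKM (4.71-fold above liver), the aspartic protease Napsa at 3128 FPKM (11.2-fold above parathyroid) and the kallikrein Klk1 at 2882 FPKM (4.14-fold above colon, 4.03 to 4.25). Fxyd2, the gamma subunit of the sodium pump, was at 2826 FPKM, Ndrg1 at 2677 FPKM, the phosphate transporter gene Slc34a1 at 2478 FPKM and Miox, the enzyme of inositol breakdown, at 2423 FPKM. Umod, which encodes uromodulin (ENSMUSG00000030963, chromosome 7, 119462711 to 119479282), was at 2297 FPKM and 16.3-fold above liver. The calcium-binding protein gene S100g was at 1474 FPKM, osteopontin (Spp1) at 1313 FPKM and collectrin (Cltrn) at 1237 FPKM. Without the liver library the ratio to the next tissue of the same table, with 0.1 FPKM added, was 528 for Miox, 333 for Slc34a1, 274 for Umod, 59.8 for Kap and 11.7 for Pck1. With the 6 further tissues added and liver left out, Pck1 was at 2.91 times the next tissue. With median-of-ratios size factors Kap and Pck1 were at 2.81 and 2.69 times the highest other tissue and left the list, as they did with upper quartile scaling (3.69 and 3.52 times).

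The liver library was the highest other tissue for 119 of the 263 genes, and without it 391 genes passed. Among the 99 enriched genes at 100 FPKM or more, the liver value was a median of 5.29% of the kidney value, against medians of 0 to 0.516% in the 11 other tissues of the table. Counting error alone put the lower bound of the fold under 4 for 58 of the 263 genes. Against the authors' deposited mean of 3 kidney libraries, which includes the single one used here, 262 genes passed, of which 244 were shared. Against the mean of the 2 remaining kidney libraries, 267 passed and 237 were shared, with Klk1 at 3.29-fold and Pck1 at 3.89-fold falling short. Over 7899 genes with a kidney FPKM of at least 10, the kidney library and that mean differed by a median of 0.09 on the log2 scale, and over 193 enriched genes among them by a median of 0.18.

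Adding the 6 tissues of the second table, with FPKM recomputed from their counts by the formula of the first table, left 208 of the 263 genes. Of the 55 genes that no longer passed, 26 had intestine as the highest of the 6 tissues, 10 had bone, 7 lung, 6 BAT, 4 skin and 2 spleen. Cubn was at 81.3 FPKM in intestine beside 119 FPKM in kidney, and Slc5a12 at 54.7 FPKM beside 148 FPKM. Spp1 reached 502 FPKM in bone and Pck1 1339 FPKM in BAT. The tables were normalized separately by the authors, so these levels rest on the recomputed scale.

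Marker lists of nephron segments, fixed before the data were examined, differed in how far kidney stood above the other tissues of its table. Thick ascending limb genes were highest in kidney for 11 of 11 members, and 9 of 11 were enriched. Among these were Umod, the loop-diuretic target Slc12a1 (17.3-fold above liver), the potassium channel gene Kcnj1 (26.8-fold) and Egf (18.6-fold above WAT). The early proximal tubule list had 12 of 12 members highest in kidney and 9 enriched, among them Slc5a2 (29.2-fold), Slc34a3 (45.7-fold) and the endocytic receptor Lrp2 (17.7-fold above WAT). With the 6 tissues added, 6 of its 12 members remained enriched, and Slc7a7 was at 187 FPKM in intestine against 178 FPKM in kidney. Both lists had medians above all 10000 random lists matched on mean expression (log2 ratio to the highest other tissue 4.03 for thick ascending limb and 4.23 for early proximal tubule). The matched random lists had typical medians of -4.20 and -2.66. The members were chosen as markers of kidney cells, so a place above random genes was built in and adds no evidence. The liver library limited these values: without it the medians were 5.56 and 5.92, and the folds were 277 for Umod, 306 for Slc12a1, 838 for Kcnj1, 245 for Slc5a2 and 89.0 for Slc34a3. No intervals were computed for folds without liver, and that of Kcnj1 rests on only 0.147 FPKM in thymus.

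The distal convoluted and connecting tubule list had 4 of 10 members enriched, namely Slc12a3, the calcium channel gene Trpv5 (47.1-fold), Klk1 and the homeobox gene Emx1 (22.7-fold), and its median log2 ratio was 1.29. Parvalbumin (Pvalb) was at 38.8 FPKM in kidney and 9574 FPKM in skeletal muscle. The intercalated cell list had 4 of 12 enriched and a median of 1.12, with the proton pump subunit gene Atp6v1b1 17.6-fold and the anion exchanger gene Slc4a9 43.1-fold above the next tissue. Slc4a1 was enriched among the 13 tissues (23.2-fold above liver) but reached 2272 FPKM in bone against 45.0 FPKM in kidney. The principal cell list had 1 of 10 enriched, Aqp2, the vasopressin-regulated water channel gene, at 98.0 FPKM and 8.86-fold above liver, with a median of -0.60. Without the liver library the fold was 28.0 for Aqp2, 126 for Trpv5, 157 for Emx1, 77.1 for Slc4a9 and 65.1 for Slc4a1, while the medians of these 3 lists were unchanged. The fold of Trpv5 rests on 0.0911 FPKM in eye, the next tissue, and is imprecise. Scnn1b, an epithelial sodium channel subunit gene, was at 40.4 FPKM in kidney and 85.5 FPKM in the parathyroid library, which also held thyroid transcripts. The podocyte list had 2 of 12 enriched, among them nephrin (Nphs1, 9.28-fold above eye), with a median of -1.19 at percentile 97.0 of random lists. The medians of the late proximal, distal and intercalated lists also lay above all 10000 random lists, and that of principal cells was at percentile 99.98. Random lists had typical medians of -2.23 for podocytes and -3.41 for principal cells, so lists with negative medians still ranked high. These percentiles follow from the choice of kidney markers and add no evidence.

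In the late proximal tubule list, 3 of 8 members were enriched (Kap, Napsa and Slc22a13, the last 43.0-fold above liver), with a median log2 ratio of 0.31 (-0.0470 with median-of-ratios size factors, with which Kap was not enriched, and 2.75 without the liver library, where Slc22a13 was 302-fold). That 302-fold value rests on 0.224 FPKM in colon, the next tissue, and is imprecise. Slc7a13, an amino acid transporter gene of this segment, was at 1.27 FPKM in kidney and 22.4 FPKM in the liver library. Cyp7b1 was at 1.69 FPKM in kidney and 139 FPKM in liver, and Slc22a30 at 5.90 and 96.3 FPKM. Slc7a13 and Cyp7b1 are known to be higher in male mouse kidney, so their low values cannot be separated from the sex of the RNA.

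**Figure D2:**
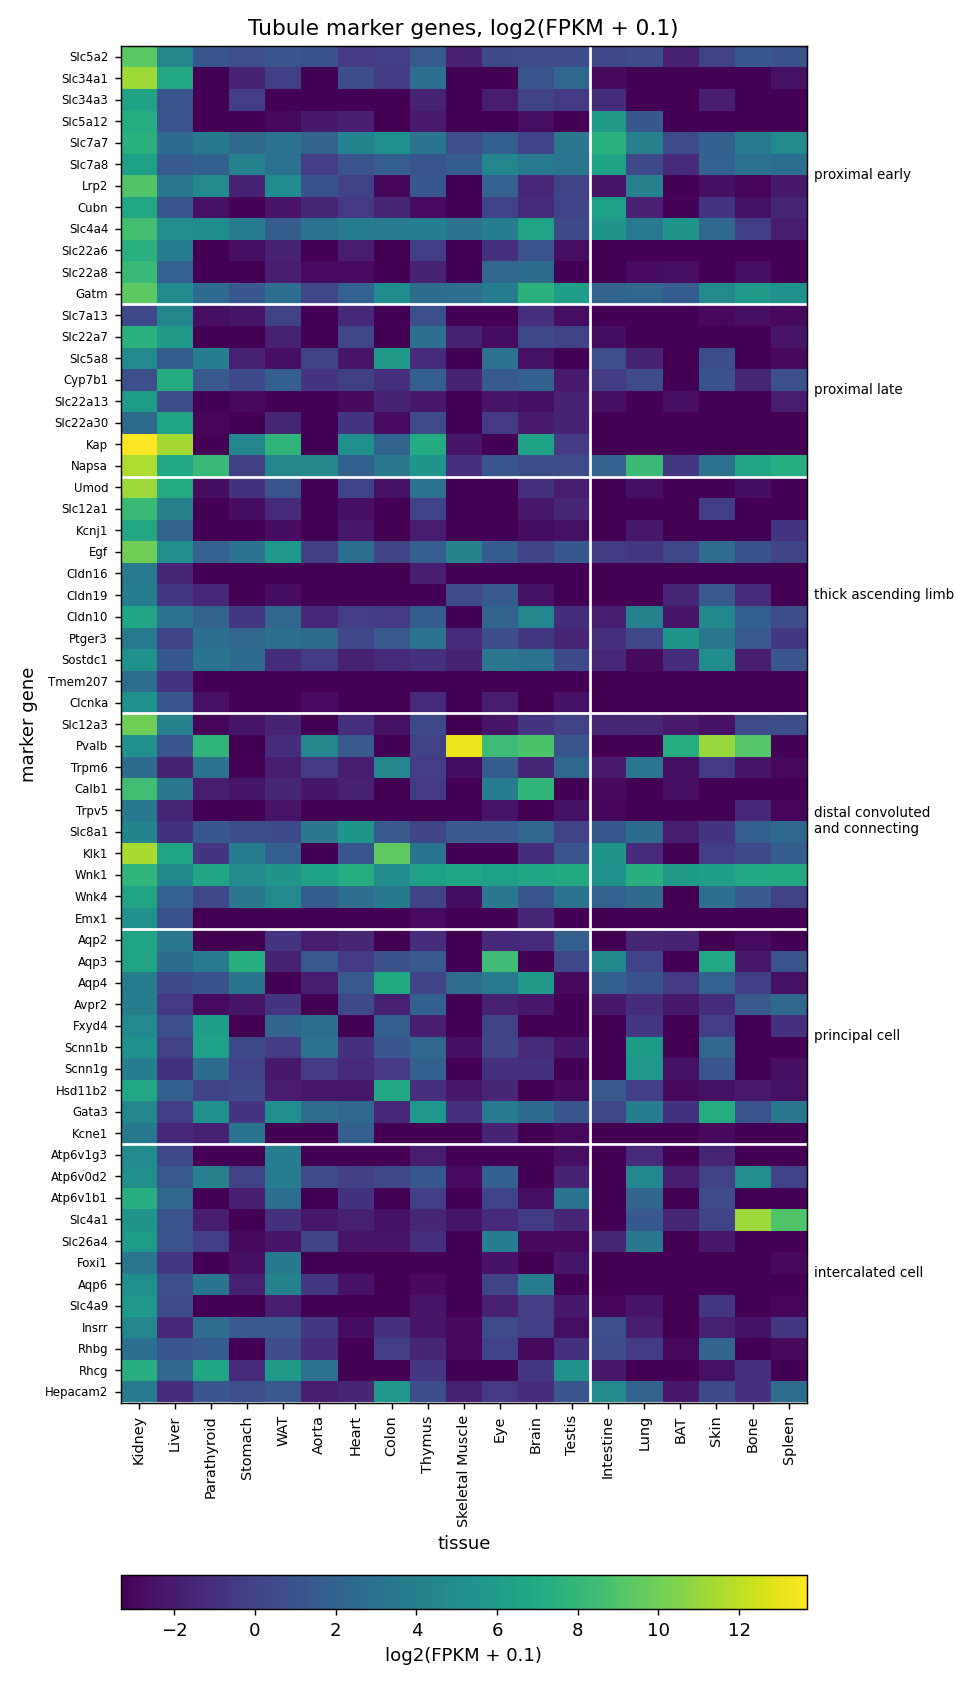
Color shows log2(FPKM + 0.1) of the tubule marker genes (rows, grouped by list) in 19 tissue libraries (columns), with 1 library each. Columns right of the vertical line come from the second table with FPKM recomputed from counts. Kidney is the highest column for 10 of 12 early proximal and 10 of 11 thick ascending limb rows.

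Transporter and metabolic lists divided in the same way. Organic ion transporter genes had 13 of 21 members enriched and a median log2 ratio of 2.25, among them the urate transporter gene Slc22a12 (660 FPKM, 9.09-fold above liver), Slc22a2 (9.80-fold) and Slc22a6 (12.3-fold). Without the liver library that median was 4.84 and these folds were 182, 21.4 and 90.3. Slco1a1, also known to be higher in male mouse kidney, had 0 reads in kidney and 208 FPKM in liver. Amino acid transporter genes had 7 of 17 enriched among the 13 tissues and 3 of 17 among 19, since Slc7a9, Slc6a19 and Slc7a7 were higher in intestine than in kidney and Slc3a1 was within 4-fold of kidney there. The gluconeogenesis and fructose list had 1 of 10 enriched, Pck1, and a median of 0.14, which was -0.60 with size factors, -0.0130 with the mean of the other 2 kidney libraries, -0.0118 with 6 tissues added and 2.48 without the liver library. The glucose-6-phosphatase gene G6pc was at 358 FPKM in kidney and 399 FPKM in liver.

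Of the endocrine and mineral list, 3 of 11 members were enriched, namely renin (Ren1, 30.8-fold above liver), Cyp24a1 and the parathyroid hormone receptor gene Pth1r (520 FPKM, 14.7-fold above liver), with folds of 177 for Ren1 and 30.1 for Pth1r without the liver library. Klotho (Kl) was at 138 FPKM in kidney and 40.5 FPKM in parathyroid, and the vitamin D 1-alpha-hydroxylase Cyp27b1 at 18.3 and 6.75 FPKM. Epo, the erythropoietin gene, had 0 reads in kidney, so its transcript was not detectable at this depth. Of 18 transcription factor genes, 1 was enriched, Emx1, and 8 were highest in kidney. Pax8 was at 48.1 FPKM in kidney and 290 FPKM in parathyroid, and Pax2 at 15.3 FPKM in kidney and 41.1 FPKM in WAT. The parathyroid library also held thyroid transcripts, with Tg taking 17.2% of its reads, and the WAT library held epididymal ones. Values in these libraries therefore cannot be assigned to parathyroid rather than thyroid, or to fat rather than epididymis. Over all kidney lists, 52 of 141 genes were enriched, and 211 enriched genes lay outside them.

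The index tau, which uses all tissues of the table, called 198 genes at tau of at least 0.9 with kidney highest and at FPKM 1 or more. Of these, 151 were also kidney-enriched, and 112 enriched genes had a lower tau. Ugt1a2 (0.997) and Slc7a12 (0.996) had values near 1, whereas Ndrg1 (0.448), Pck1 (0.581) and Fxyd2 (0.725), which are transcribed in many tissues, did not. The tau count was 121 with a kidney level of at least 5 FPKM and 441 on linear FPKM.

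Under the same rule kidney ranked 8 of 13 tissues in enriched genes. Testis had the most, 4467, led by the protamine gene Prm2, followed by brain (681, myelin basic protein Mbp), eye (665, the lens gene Crybb2), thymus (650), colon (432), liver (400, albumin Alb) and WAT (340). Below kidney came aorta (235, Tagln), skeletal muscle (159, Acta1), stomach (125, Pgc), heart (120, Myl2) and parathyroid (79, Tg). The enriched genes with the highest FPKM were Scgb1a1 in thymus, the immunoglobulin gene Igkc in colon and Crisp1 in WAT. Scgb1a1 marks airway cells and was at 2337 FPKM in thymus and 39398 FPKM in lung. With the 6 further tissues every count fell, for example to 113 in colon, 246 in thymus, 85 in skeletal muscle and 149 in aorta. Parathyroid fell to 50, eye to 438 and kidney to 208, which ranked 9 of 19. Over all alternatives, 13 of 64 tissue counts moved by more than 1.5 times.

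**Figure D3:**
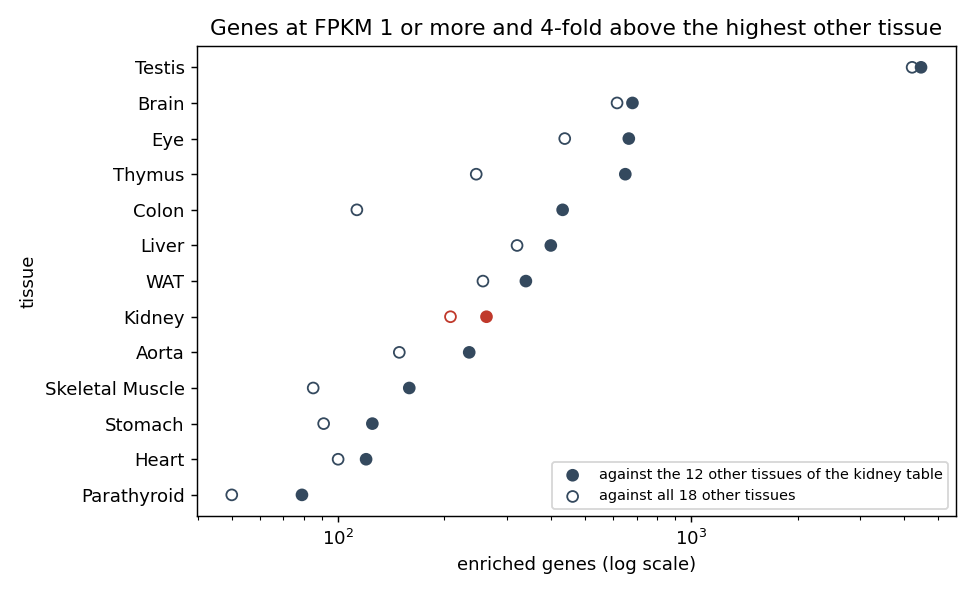
Number of enriched genes per tissue on a log scale, against the 12 other tissues of the kidney's table (filled) and against all 18 others (open), with kidney in red. Kidney had 263 and 208 genes, and testis 4467 and 4215.

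Genes shared by kidney and exactly 1 other tissue numbered 210, and liver was the partner for 109 of them. Among the most abundant of these in kidney were the fatty acid transporter gene Slc27a2 (2913 FPKM in kidney, 1044 FPKM in liver) and argininosuccinate synthase (Ass1, 2295 and 3791 FPKM). Colon shared 27 genes, led by Spink1 (986 and 674 FPKM), Calml4, the microvillus gene Vil1 (186 and 675 FPKM) and Baiap2l2, and all 4 were higher in intestine than in kidney. WAT shared 20 genes, led by the glutathione peroxidase gene Gpx3 (27474 and 7924 FPKM), Slc22a5, Wfdc15b (225 and 1432 FPKM) and Serpina1f (126 and 801 FPKM). The WAT library also held epididymal genes, which took 2.13% of its reads. Sharing with fat therefore cannot be told apart from sharing with epididymis. Testis shared 19 and parathyroid 16, and the parathyroid library also held thyroid transcripts. Without the liver library 157 genes were shared, and colon led with 45 of them. With liver kept in, the total ran from 147 with the 6 tissues added to 242 with median-of-ratios size factors. Liver led in both, with 75 and 144 genes.

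Across 26586 genes at FPKM 1 or more in any of the 13 tissues, the kidney profile was closest to liver by Spearman correlation (0.879), followed by parathyroid (0.855), stomach (0.848), WAT (0.836) and aorta (0.834). Testis was farthest (0.457), after brain (0.765) and eye (0.777). These coefficients are across genes, which are not independent replicates. By Pearson correlation of log2(FPKM + 1) parathyroid came first (0.850). The parathyroid library also held thyroid transcripts, so its coefficients are not those of parathyroid tissue alone. The liver library held nephron markers at a median of 3.45% of kidney, against 0.0371% for the median of the 17 other tissues. How far these transcripts raise the coefficient of liver was not tested.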

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

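All tests in this part were chosen after the values they weigh had been seen. The authors' deposited mean of 3 kidney libraries, which no comparison of the report uses as its main value, held Xist at 93.1 FPKM, far above the level of 3 reads. The mean of the 2 remaining kidney libraries held 94.2 FPKM, with the 4 Y-linked genes summing to 0.00931 FPKM.

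The kidney and eye libraries carried Xist but almost no Y-linked transcripts, although every sample is labelled male. Loss of Y-linked reads in the authors' counting is argued against, since the lowest Y-linked sum among the 17 other tissues was 35.7 FPKM. RNA of female animals in the kidney and eye libraries is a candidate explanation: the higher of their Y-linked sums was 0.131% of the median of the other tissues, and Slc7a12, which is known to be higher in female mouse kidney, was at 173 FPKM with the male-biased Slc7a13 at 1.27 FPKM. In the aorta and parathyroid libraries RNA of both sexes may be present, as the lower of their Y-linked sums was 33.5% of that median beside Xist at 22.1 and 59.7 FPKM. Whether the labels or the tissue pools differ stays open, and sex was not tested as a biological factor because all samples are labelled male.

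Transcripts of 6 nephron segment lists, the late proximal one not included, appeared in the liver library at a median of 3.45% of kidney over 39 markers at FPKM 10 or more and highest in kidney when liver is left out, against 0.0371% for the median of the 17 other tissues. Carry-over from the kidney library of this series is argued against by 3 of the 99 enriched genes at 100 FPKM or more, whose liver reads were under 10% of those at the median ratio of 5.29%: Ugt1a2 had 0 reads where 459 would be brought, and Slc7a12 had 0 where 181 would be. RNA of a male kidney in the liver library may be the source, since the male-biased kidney gene Slc7a13 was 17.6-fold higher in the liver library than in the kidney library. Transcription of kidney genes by liver cells cannot be told apart from it: the medians of 5 segment lists with at least 3 genes differed by 2.01-fold at most, but single markers differed by 10.1-fold, from 1.12% (Nphs1, with 1.04% for the median of the 17 other tissues) to 11.3% (Aqp2), and 10 of 39 lay outside 2-fold of the median.

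The aorta library held 13 markers of thyroid and parathyroid at a median of 8.72% of the parathyroid library, with medians of 8.93% for parathyroid and 8.70% for thyroid genes. Transcription of these genes in the aorta wall is argued against, since the ratios of all 13 markers lay within 1.504-fold of each other, from 7.46 to 11.2%. Thyroid and parathyroid tissue in the aorta RNA is therefore a candidate explanation for that median of 8.72%. Carry-over from the parathyroid library cannot be told apart from it: that ratio would bring 5.21 FPKM of Xist to the aorta library, which held 22.1 FPKM, so Xist sets no limit on it.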

How the results depend on the processing

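No paired analysis was possible because each tissue has 1 library with its own column and no result comes from a test. Of 59 alternatives to the main counts and coefficients, 46 stayed close to the main value (counts within 1.5 times). Among these were every change of pseudocount or scaling for the 263 kidney-enriched genes and the single tissues left out (267 to 391 genes). Close counts did not mean the same genes: 208 of the 263 passed with pseudocount 1, 225 with median-of-ratios size factors and 235 with upper quartile scaling. The 391 genes without Liver lay near the limit of 1.5 times and held 128 further genes. The count was 131 at 10-fold and 598 against the second highest tissue, as those rules are stricter and looser. Without Liver and Aorta it was 405. The 198 tau genes became 358 at tau of at least 0.8, 441 on linear FPKM and 121 at level 5. Kidney's rank of 8 became 9 with median-of-ratios size factors, 9 with 6 tissues added and 6 without Liver. The closest tissue's coefficient of 0.879 became 0.850 by Pearson and 0.855 without Liver, with parathyroid closest in both. The 52 enriched list genes became 126 against the median of the other tissues. Tissue markers in their own library were 104 of 108 in the kidney's table alone.

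List medians of the log2 ratio changed sign in 8 of 72 cases, moved by more than 0.1 without a change of sign in 40 and stayed within 0.1 in 24. Against the median of the other tissues they were 1.998 for podocyte, 5.39 for principal cell and 5.64 for transcription factor genes. With size factors they were -0.0470 for late proximal and -0.60 for gluconeogenesis genes. The gluconeogenesis median was -0.0130 with the other 2 kidney libraries and -0.0118 with 6 tissues added, where the amino acid transporter median was -0.20. Where no rule is named, the cause was not tested. Of the 24 genes named by ratio or level, 17 passed in all 29 alternatives. The alternatives that use other kidney libraries, recomputed FPKM, or leave out Liver except in the planned single-tissue series were chosen after seeing the data, as were Liver and Aorta together and the markers of 1 table. Comparing separate kidney columns was not run, as 1 kidney library has its own column here. A floor of 3 reads limits genes near 0.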

Other observations

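The values in this part were chosen after the data had been seen, except for the lists of other organs and cells. In the WAT library the 5 epididymal genes had a median of 1753 FPKM and took 2.13% of all reads. The same library held transcription factor genes of the kidney lists: Pax8 was at 127 FPKM, Emx2 at 49.0 FPKM, Pax2 at 41.1 FPKM and Foxi1 at 11.7 FPKM, against 48.1, 33.4, 15.3 and 9.94 FPKM in kidney. The defensin gene Defb29, shared by kidney and WAT alone, was at 199 FPKM in WAT and 43.7 FPKM in kidney.

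In the thymus library 8 lung markers stood at a median of 7.97% of the lung library (5.93 to 9.80%), and 10 liver markers at a median of 1.47% of the liver library. In the heart library the same lung markers were at a median of 0.589% and the liver markers at 0.417%.

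Kidney held little of the other organs listed. The medians were 0 FPKM for adrenal (highest member Star, 0.557 FPKM), 0 FPKM for pancreas (Ins2, 0.356 FPKM) and 0 FPKM for epididymis (Adam7, 0.0311 FPKM). The thyroid list had a median of 2.34 FPKM in kidney, with the deiodinase Dio1 at 91.1 FPKM. That list shares Slc26a4 (62.7 FPKM in kidney) and Pax8 with the kidney lists, and Dio1 was at 139 FPKM in liver. These values are therefore no sign of thyroid tissue in the kidney library. Endothelial genes had a median of 16.9 FPKM in kidney and 119 FPKM in lung, immune genes 9.26 FPKM in kidney and 514 FPKM in spleen, and erythroid genes 33.0 FPKM in kidney and 9334 FPKM in bone. Early response genes had a median of 3.87 FPKM in kidney and 28.7 FPKM in eye. Among enriched genes at FPKM 10 or more that are not predicted models, Slco1a6 differed most between the kidney library (189 FPKM) and the mean of the other 2 kidney libraries (70.7 FPKM), by 1.41 on the log2 scale.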
